A study of Pan paniscus and Pan troglodytes with 4 samples.

How the data were processed

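Induced pluripotent stem cell lines were made from stored blood cells of 2 bonobos and 1 chimpanzee with RNA vectors (SRV) that carry reprogramming factors, per the labels' protocols. They were grown on mouse embryonic fibroblasts whose division had been stopped, in a medium with the Wnt pathway inhibitor IWR-1. Directional libraries of total RNA were read as paired ends on an Illumina NovaSeq, per the labels' protocols. Which vector made which line is not given in the sources used here. The labels place 3 lines in the bonobo group, 1 of a female and 2 of 1 male, and 1 line of a female in the chimpanzee group. Replicate numbers follow accession order and pair no samples.

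Trim Galore, STAR, bedtools and HISAT2 and the builds hg38 and panTro6 are named per the submitters' processing notes, with no version or role, so the aligner and build behind each table are not given in the sources used here. Genes of both species may therefore have been read against a genome of another species. The deposited gene table holds TPM, and each column sums to the full TPM total over the 16243 genes listed, so every value is relative to those genes. The deposited retrotransposon table holds RPM for 647 families, with column totals of 9077, 9513, 6600 and 7587 RPM, so RPM refers to a larger set of reads. Low RPM values were checked for whole reads: of values under 10 steps, 76.8 to 81.5 percent were whole multiples of the commonest value within 0.02 steps and 97.0 to 99.1 percent were multiples of a sixth part of it, so reads were split between families and whole reads were not recovered. Counting intervals were therefore not computed. Symbols were matched to the RefSeq annotation of bonobo assembly NHGRI_mPanPan1-v2.0 for 16021 genes (98.6 percent), which was used for gene order alone.

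Values were taken to log2 with a pseudocount of 1 TPM or 1 RPM, and genes or families with a mean of at least 1 over the libraries were tested. For the species, values were averaged within each animal, and 2 bonobo animals were set against 1 chimpanzee with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg). The lone chimpanzee is thereby assumed to vary like the bonobo animals, and the average hides the spread between the male's lines. Sex was not corrected for: the bonobo animals were of both sexes and the chimpanzee was female. For the bonobo animals, the female line was set against the male's 2 lines, whose spread is between clones of 1 animal. Genes were called at an adjusted p under 0.05 and at least 1 log2 unit, families at 1.5-fold. A library stood apart at a gene where it lay that far beyond the nearest of the other 3. Camera was run with a preset correlation of 0.01 on lists with at least 3 tested members, 18 of 22 gene lists and 10 of 12 family lists. These lists were tested again by camera with an estimated correlation and by fry. Those fits held 3 columns of values and 2 coefficients, which leaves too little spread to estimate a correlation. Missing camera with an estimated correlation was therefore nearly fixed beforehand, and no conclusion is drawn from it. Medians of lists between single libraries were set against 10000 random lists matched on mean expression, whose genes were drawn independently. Python 3.11.15 with pandas 2.3.3 drew the figures and placed genes in order.

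The tests, the lists and most alternatives were chosen before the data were examined. Camera on family lists between the bonobo animals was added afterwards. Genes named in the text were the 12 with the largest difference in each direction among those that passed and lay outside the range of the other group's lines, all that passed where fewer did, followed by others by size up to 6. Members of a fixed list that passed, and genes and families set beforehand, were named too, and for families the number was 8 per direction. POU5F1B, RPS18, DDX39B, PPP1R10, TUBB, RNF5, GTF2H4, PPP1R11, CDKN1A, GDF15 and the further examples of the closing section were chosen after their values were seen. Lists of mitochondrial transcripts, Y-linked genes, replication histones and L2 and MIR repeats were not analysed here, and the list for antigen presentation had 2 tested members, too few for a test. On simulated data with 200 of 12061 genes changed, the species test recovered 79.2, 90.4 and 99.1 percent at log2 differences of 1.5, 2 and 3, with 5.53 percent false calls. The test between bonobo animals recovered 72.7, 87.3 and 98.1 percent with 8.89 percent false calls. With 40 of 280 families changed, these shares were 91.4, 98.5 and 100 percent for the species and 34.3, 54.6 and 80.0 percent for the animals. The simulations drew the spread from the fitted trend, so they do not test that trend. Alternatives covered the pseudocount, the filter, the scaling, the trend, the replicate unit, each bonobo line left out, the fold minimum and the set test.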

Results

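Total RNA was sequenced from 4 lines of induced pluripotent stem cells, which are blood cells returned to an embryo-like state by reprogramming factors. Of the 3 bonobo lines, 1 came from a female and 2, here called B1 and C6 for short, from the same male. The chimpanzee line came from a female. The gene table listed 16243 genes in TPM, a measure of transcript abundance relative to all listed genes, of which 12061 had a mean of at least 1 TPM and were tested. The retrotransposon table listed 647 repeat families in RPM, read numbers scaled to sequencing depth, of which 280 had a mean of at least 1 RPM. TPM keeps no depth, so the depth behind a gene's value is unknown. The commonest step of the low RPM values was 0.0543, 0.0569, 0.0541 and 0.0609 RPM in the bonobo female line, B1, C6 and the chimpanzee line, which sets the depth if 1 step is 1 read.

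Transcripts of the pluripotency network were abundant in all 4 lines. SOX2, a transcription factor of the network, stood at 383 ± 63.2 TPM (SD, n = 3 lines) in bonobo and 486 TPM in the chimpanzee line. NANOG stood at 45.1 ± 1.59 and 52.9 TPM, and the RNA-binding protein gene LIN28A at 407 ± 37.8 and 431 TPM. DNMT3B, a DNA methyltransferase, reached 831 ± 112 and 1099 TPM. MYC was at 133 ± 4.58 and 125 TPM, and ZIC2, a marker of the primed state, at 422 ± 71.4 and 453 TPM. KLF4 was at 13.8 ± 1.14 and 19.8 TPM. KLF17, a marker of the naive state, was listed at 0 in the 3 bonobo lines and at 0.0163 TPM in the chimpanzee line. KLF17 was below the filter, and none of the other genes passed the tests between species or animals. XIST, XACT, DDX3Y and RPS4Y1 were not analysed here. Across genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.980 to 0.983 between bonobo lines and 0.963 to 0.972 between bonobo and chimpanzee lines.

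POU5F1, the central pluripotency factor, was listed at 9.07 ± 0.484 TPM in bonobo and 8.95 TPM in the chimpanzee line, below its retrogene POU5F1B at 17.6 to 22.8 TPM. Reads of the pair can be shared, so both values are uncertain. Its neighbours were low too. Of the 105 listed genes from TRIM27 to DAXX, an interval that holds the major histocompatibility complex, 86 had a mean under 1 TPM and 34 were listed at 0 in all 4 libraries. RPS18, a ribosomal protein gene, was listed at 0 in every library, as were DDX39B and PPP1R10. The 4 genes with a mean of at least 10 TPM were the tubulin gene TUBB, at 128 to 149 TPM, RNF5 at a mean of 59.2 TPM, GTF2H4 at 12.5 and PPP1R11 at 11.3 TPM. Gene order was taken from the bonobo assembly, and the ends of this interval were set after the values were seen.

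**Figure D1:**
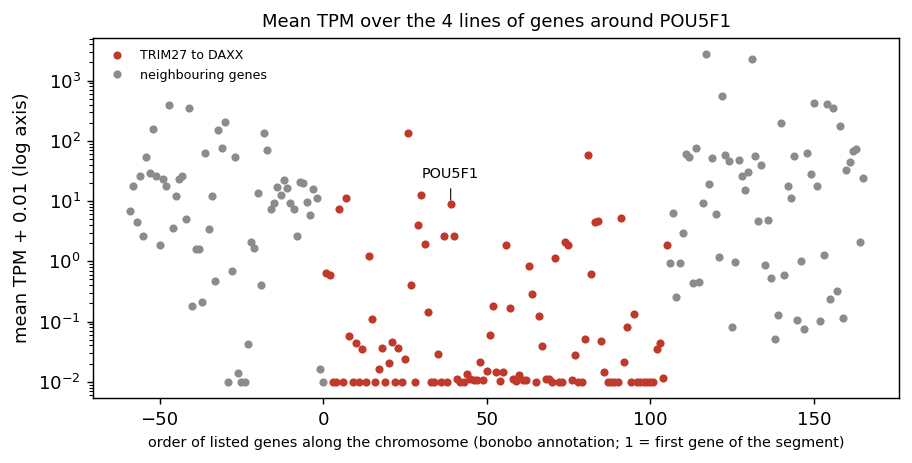
Mean TPM over the 4 lines (log axis, 0.01 added) of POU5F1 and its listed neighbours, in the order of the bonobo annotation. Points from TRIM27 to DAXX are red and genes on either side are grey; 86 of the 105 red points lie under 1 TPM.

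The comparison of the species asked which transcripts differ between bonobo and chimpanzee pluripotent cells. SPP1, which encodes the secreted phosphoprotein osteopontin, was 7.75-fold lower in bonobo, at 195 ± 6.59 TPM (SD, n = 3 lines) against 1520 TPM in the chimpanzee line (limma adjusted p = 0.000173). GRAMD2A was 16.3-fold higher in bonobo, at 33.5 ± 2.77 against 1.07 TPM, and STYXL1 was 8.00-fold higher, at 39.2 ± 5.79 against 4.09 TPM (limma adjusted p = 0.00415 for both). Folds are on the log2(TPM + 1) scale, which understates changes of low genes. In all, 219 genes passed limma on the means of 2 bonobo animals and 1 chimpanzee, 129 higher and 90 lower in bonobo, and at 217 of them the chimpanzee line lay outside the range of the bonobo lines. With each line as its own replicate 40 passed, all among the 219, 21 higher and 19 lower. Without the female line the male's 2 lines served as the replicates, so the unit changed too, and 197 passed, 90 higher and 107 lower, 144 of them among the 219. Without male line B1 1 gene passed, SPP1 (limma adjusted p = 0.0199), with 2095 at an unadjusted p under 0.05 against 2350 with all lines, and the log2 difference was 4.02 for GRAMD2A and 3.10 for STYXL1 against 4.03 and 3.00. Without C6 106 passed, after quantile normalization 77 and after median-ratio scaling 333. Without the intensity trend or without the filter on low values limma called 0, with 2029 and 2296 genes at an unadjusted p under 0.05.

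Some of the genes with the largest differences also passed with lines as replicates, among them SPP1, GRAMD2A and STYXL1. KCNK17, a potassium channel gene, stood at 18.9 ± 3.38 TPM in bonobo against 2.02 TPM, and the protease inhibitor gene SPINK5 at 10.8 ± 0.813 against 0.952 TPM (limma adjusted p = 0.0316 for both with lines as replicates). Lower in bonobo were SCG2, a secretory granule protein gene, listed at 0.320 TPM in the female line, 0 in B1 and 0.193 in C6 against 12.7 TPM, and PECAM1, an endothelial adhesion molecule gene, at 0.182 ± 0.0690 against 11.7 TPM. ARHGAP36 was at 3.47 ± 1.16 against 30.5 TPM. AHSP, which encodes a chaperone of haemoglobin alpha chains, was listed at 0 in the 3 bonobo lines and at 6.44 TPM in the chimpanzee line, and FEZF1 at 0, 0 and 0.158 against 7.65 TPM. Other genes passed on animal means while the lines of the male lay far apart. TFF1, a secreted trefoil peptide gene, was at 36.4 TPM in the female line, 243 in B1 and 5.72 in C6, and was listed at 0 in the chimpanzee line. TNNI2 and TNNC2, genes of fast skeletal muscle troponin, were at 24.9 and 92.2 TPM in B1 but at 0.557 and 5.73 in C6, with 0 and 3.94 in the chimpanzee line. With lines as replicates the limma adjusted p was 0.250 for TFF1, 0.429 for TNNI2 and 0.436 for TNNC2. The remaining genes higher in bonobo on animal means were RFPL2, PLEKHA2, DKK4, CD7 and FAM162B, and those lower were SIX6, BTBD17, SLC16A12, MILR1, LHX5 and FEZF2. None of these passed with lines as replicates, where their limma adjusted p ranged from 0.0517 for CD7 and SLC16A12 to 0.146 for RFPL2.

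**Figure D2:**
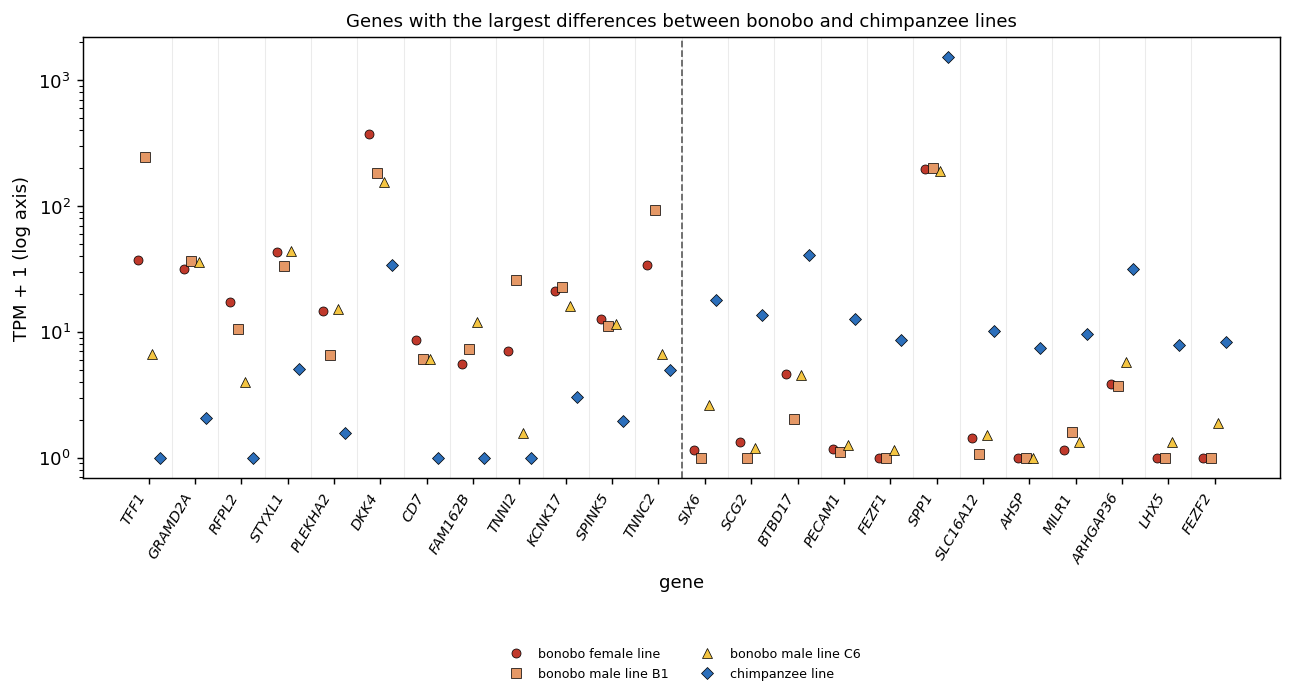
TPM + 1 (log axis) in each of the 4 lines for the 12 genes with the largest positive and the 12 with the largest negative differences that passed limma on animal means, separated by the dashed line. Each point is 1 library; the chimpanzee line lies outside the bonobo range at each gene, and TFF1 spans 5.72 to 243 TPM within the male's 2 lines.

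The chimpanzee library lay at least 1 log2 unit beyond the nearest other library at 301 genes, 147 higher and 154 lower. The same count was 81 for the female bonobo line, 72 for B1 and 21 for C6. B1 and C6 each had the other line of the same male among the libraries compared, which holds their counts down. The female line had other bonobo lines among them, while the chimpanzee line had no other line of its species. With a pseudocount of 0.1 TPM the counts were 474 for the chimpanzee line, 148 for the female line, 174 for B1 and 74 for C6, and at a mean of at least 5 TPM they were 190, 52, 40 and 10.

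Of the 22 gene lists fixed beforehand, 18 had enough tested members, and 9 passed camera with a preset correlation of 0.01. None passed with an estimated correlation (lowest adjusted p = 0.561) or with fry (lowest adjusted p = 0.269). With 2 bonobo animals and 1 chimpanzee, too little spread is left to estimate that correlation. Missing the first of these tests therefore says little about a list. Genes of mesendoderm, the layer that gives rise to endoderm and mesoderm, were higher in bonobo: 8 of 15 rose past the test, 1 fell and 6 did not pass (camera from limma, adjusted p = 7.79e-05, and adjusted p = 0.561 with an estimated correlation). Adjusted over the list alone, 9 were higher and 1 was lower. CER1, a secreted antagonist of Nodal and BMP signals, was at 2147 TPM in the female line, 2420 in B1 and 1186 in C6, against 585 TPM in the chimpanzee line. The homeobox gene GSC was at 306, 346 and 156 against 70.5 TPM, and MIXL1 at 534, 533 and 354 against 195 TPM. EOMES, GATA6, FOXA2, CXCR4 and APOA2 were the others higher in bonobo, and KDR, a receptor of vascular growth factor, was lower. Within the male, B1 lay above C6 at 11 of the 15 genes, by a median of 1.03 log2 units. With lines as replicates none of these 9 genes passed limma, the lowest adjusted p being 0.106 for MIXL1. Without B1 the list itself did not pass camera from limma (adjusted p = 0.268).

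**Figure D3:**
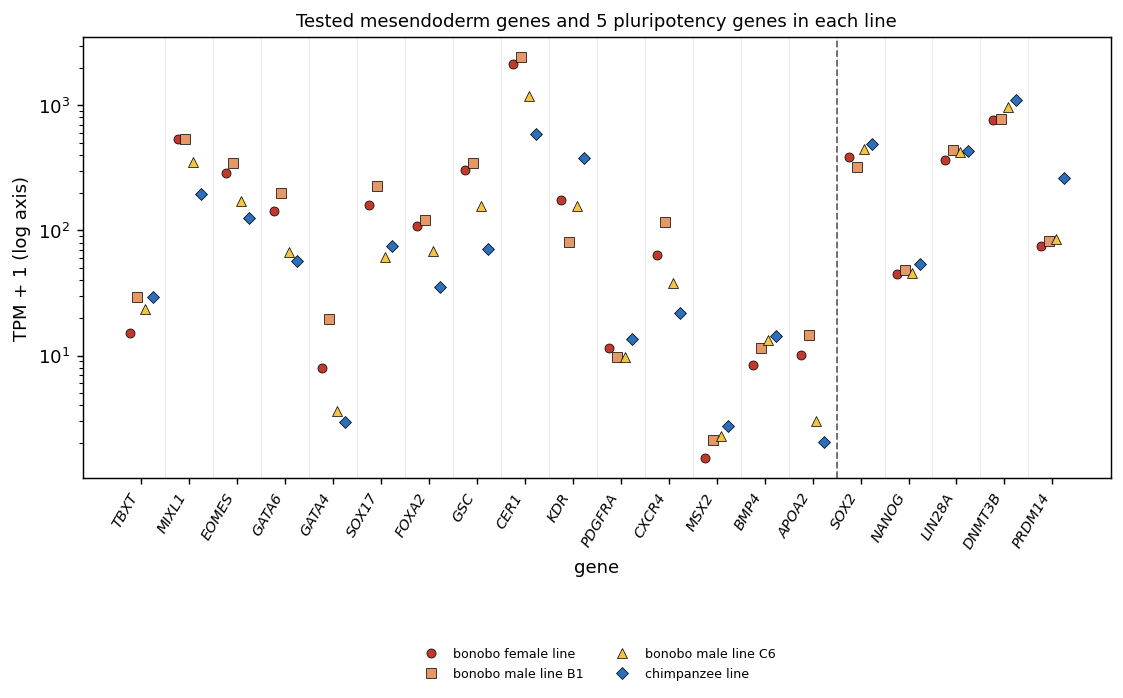
TPM + 1 (log axis) in each of the 4 lines for the 15 tested mesendoderm genes, left of the dashed line, and 5 pluripotency genes. Each point is 1 library; CER1 runs from 585 TPM in the chimpanzee line to 2420 TPM in bonobo male line B1.

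Neuroectoderm genes were lower in bonobo, with 2 of 8 past the test, SIX6 and LHX2, both transcription factors of the forebrain and eye (camera, limma, adjusted p = 0.000931). LHX2 stood at 1.57 ± 0.497 TPM against 14.2 TPM. The core pluripotency list was lower (adjusted p = 0.00266), with a median of -0.20 log2 units over 26 genes, of which 1 passed: PRDM14, a repressor that guards the pluripotent state, at 80.1 ± 5.51 against 262 TPM. The primed list (adjusted p = 0.00729) and the list of genes on the X chromosome tied to its inactivation (adjusted p = 0.0159) were lower with 0 members past the test of 19 and 17. Imprinted genes were lower (adjusted p = 0.0238) with 1 of 21 past it, DLK1, at 3.28, 2.62 and 17.0 against 28.2 TPM. Glycolysis and hypoxia genes were higher (adjusted p = 0.0154) with 2 of 26, the mitophagy receptor gene BNIP3 at 181 ± 29.8 against 62.5 TPM and the lactate exporter gene SLC16A3. Interferon response genes were higher (adjusted p = 0.0412) with 1 of 16, BST2, an antiviral tether. Each of these adjusted p-values was 0.561 with an estimated correlation. C6 alone against the chimpanzee line had a median of -0.06 for the core list, at percentile 7.6 of random lists. For the other lists of this paragraph C6 lay in the direction given, at percentile 0 to 0.5 or 99.9 to 100. Glycolysis genes differed within the male too, by a median of -0.20 for B1 minus C6, against 0.15 between the species. The imprinted list also missed without the female line (adjusted p = 0.0836) or B1 (0.0529), and the interferon list without the female line (0.0507) or C6 (0.118). With lines as replicates both missed too, at an adjusted p of 0.0774 and 0.0516. Adjusted over the list alone, those lower numbered 3 for neuroectoderm, 1 for core pluripotency and 2 for imprinted, and those higher 2 for interferon. Both directions occurred in the primed list, with 1 higher and 1 lower, and in glycolysis, with 2 higher and 1 lower, and 0 passed in the X list. The bonobo animals were of both sexes and the chimpanzee was female, so the difference of the X list was not separated from sex.

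Markers of fibroblasts, a type that was present as mouse feeder cells, were lower in bonobo (camera, limma, adjusted p = 0.00942, and adjusted p = 0.561 with an estimated correlation) with 2 of 21 past the test, and 2 when adjusted over the list alone. Without C6 the list did not pass (adjusted p = 0.0912). COL6A1 was at 58.4, 29.8 and 20.9 TPM against 269 TPM, and POSTN at 20.5 ± 1.95 against 52.8 TPM. COL1A1 was at 130 ± 25.4 and 188 TPM, COL3A1 at 2.97 ± 1.39 and 3.74 TPM. Blood cell markers did not pass (adjusted p = 0.704; median -0.14, mean 0.08), with PTPRC at 0.0507, 0.0529 and 0.0611 TPM in the bonobo lines and listed at 0 in the chimpanzee line, and CD3E at 0.924 ± 0.571 and 1.07 TPM. Wnt targets did not pass (adjusted p = 0.572, lower by camera; median -0.14, mean 0.05), although DKK4 and NOTUM, both secreted Wnt antagonists, were higher in bonobo. The other lists that did not pass were naive pluripotency (adjusted p = 0.399) with CPT1A higher, the 8-cell list (0.191) with RFPL2 higher, p53 targets (0.572), cell cycle (0.819), restriction of transposable elements (0.233), ribosomal proteins (0.126) and zinc fingers (0.0818) with ZNF841 lower. In the restriction list TRIM28 stood at 1122 ± 59.2 and 1146 TPM, APOBEC3B at 5.73 ± 0.651 and 4.30 TPM, and PIWIL2 at 0.229 in the female line, listed at 0 in B1, 0.0816 in C6 and 0.253 in the chimpanzee line. Adjusted over the list alone, members higher in bonobo numbered 1 for blood, 2 for Wnt targets and 2 for 8-cell, naive had 1 higher and 1 lower, and 0 passed for the p53, cell cycle, restriction, ribosomal and zinc finger lists.

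The female and the male bonobo differed at 35 genes, 5 higher and 30 lower in the female line, with the spread taken from the male's 2 lines. ZNF22 was at 0.741 TPM in the female line against 92.9 and 102 TPM in the male lines (limma adjusted p = 2.17e-06), and 109 TPM in the chimpanzee line. ZFP42, a pluripotency marker also known as REX1, was at 0.273 against 66.5 and 44.3 TPM. ZNF560 was at 0.168 against 48.3 and 57.9 TPM and ARMCX1 at 1.48 against 60.8 and 73.7 TPM. LDOC1 and TUSC1 were listed at 0 in the female line and at 22.9 to 38.4 TPM in the male lines. KRBOX1 was listed at 0 in both the female line and the chimpanzee line and at 33.9 and 36.2 TPM in the male lines. Of the imprinted genes, NDN fell to 1.43 against 28.2 and 46.6 TPM, and NNAT to 7.43 against 99.1 and 86.0 TPM. SOX15 was at 0.596 against 40.7 and 14.6 TPM, TSPYL5 at 0.0877 against 13.3 and 15.0 TPM, and LYPD1 at 0.0361 against 8.57 and 13.8 TPM. In all, 14 of the 30 lower genes were under 1 TPM in the female line, and 1 of the 30 was under 1 TPM in the chimpanzee line.

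Higher in the female line were NLRP2, a gene of the early embryo, at 11.2 against 0.0691 and 0 TPM, the testis gene TEX13B, the lipid antigen presenter gene CD1D, DKK4 and FBN2 (limma adjusted p = 0.00566 for NLRP2 and 0.0452 for FBN2). UCN, next in size, did not pass at 8.33 against 1.53 and 0.590 TPM. Quantile normalization left 8 of the 35 calls, and 0 passed without the intensity trend or without the filter, with 556 and 771 genes at an unadjusted p under 0.05 in limma. The comparison held 1 line of the female.

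**Figure D4:**
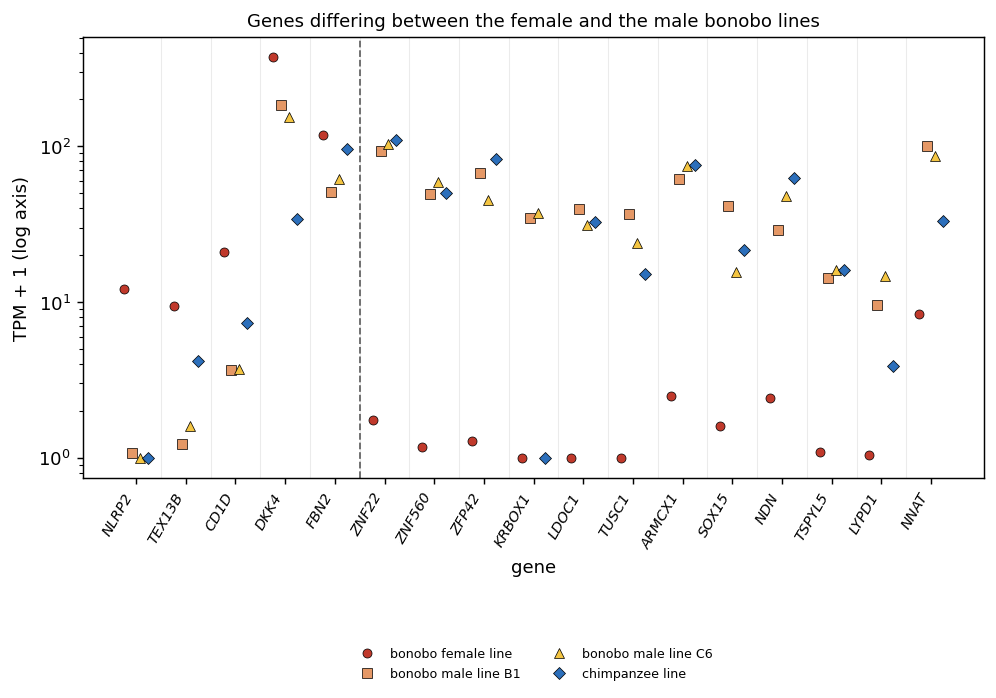
TPM + 1 (log axis) in each of the 4 lines for the 5 genes higher and the 12 genes with the largest falls in the female bonobo line, separated by the dashed line. Each point is 1 library; ZNF22 is at 0.741 TPM in the female line and at 92.9 to 109 TPM in the others.

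Among gene lists, p53 targets were higher in the female than in the male bonobo (camera, limma, adjusted p = 3.28e-08, and adjusted p = 0.823 with an estimated correlation), with 22 of 24 above the male mean, a median of 0.53 log2 units and 0 genes past the test. Adjusted over the list alone, 0 passed. CDKN1A, the p53-induced inhibitor of the cell cycle, was at 28.2 TPM in the female line, 6.87 in B1 and 20.9 in C6, and GDF15 at 9.67, 1.36 and 6.96 TPM. B1 held the lowest value of the 4 libraries at 19 of the 24 targets, and the female line held the highest at 19. The core pluripotency list was lower in the female line (adjusted p = 0.0085, and adjusted p = 0.823 with an estimated correlation), with a median of -0.12 log2 units and 0 of 26 genes past the test or past it when adjusted over the list alone. Signs differed within 4 lists that did not pass: camera was lower for naive pluripotency (median 0.05, mean -0.41), imprinted (0.04, -0.31), zinc finger (0.01, -0.04) and interferon genes (-0.05, 0.03).

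Retrotransposons were compared to ask whether reads of families of mobile elements differ in abundance between the species. RPM counts reads over repeats and does not measure the activity of the elements. HERVK11I, the internal part of an endogenous retrovirus, was 3.00-fold higher in bonobo, at 138 ± 37.0 RPM (SD, n = 3 lines) against 45.6 RPM (limma adjusted p = 3.61e-06). MER11C and MER11B, long terminal repeats tied to the same virus, were at 90.8 ± 39.5 against 32.2 RPM and 32.8 ± 10.8 against 15.3 RPM (limma adjusted p = 2.36e-05 and 0.00912). LTR17, the terminal repeat of the HERV-W group, was at 20.8 ± 3.39 against 8.83 RPM (limma adjusted p = 0.0188). These 4 were the families called on animal means, all higher in bonobo, and at each the chimpanzee line lay below all 3 bonobo lines. With lines as replicates limma called 0, with 18 at an unadjusted p under 0.05, and leaving out any 1 bonobo line also left 0. The median over families was 0.11 log2 units higher in bonobo as deposited and -0.03 after median-ratio scaling, where 19 passed, 14 higher and 5 lower, 3 of them among the 4.

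**Figure D5:**
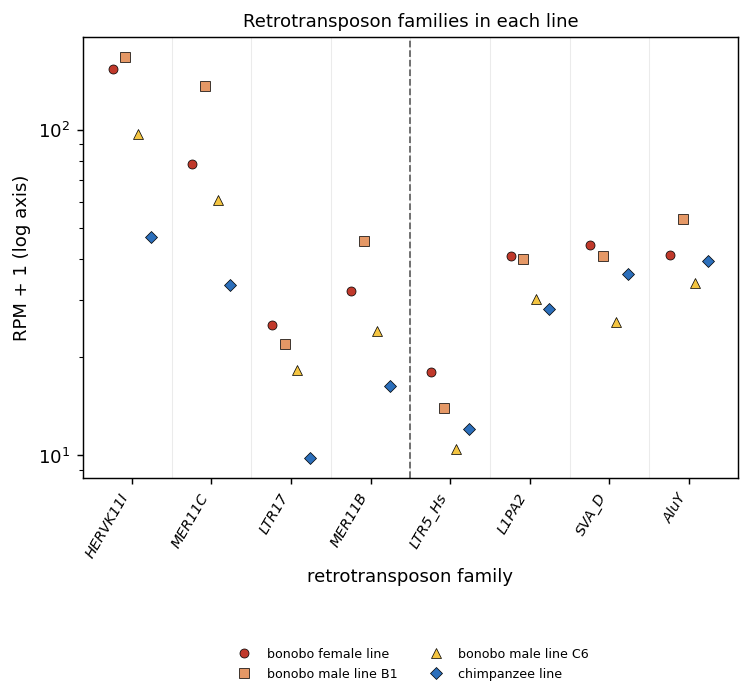
RPM + 1 (log axis) in each of the 4 lines for the 4 families called between the species, left of the dashed line, and 4 families named beforehand. Each point is 1 library; HERVK11I is at 45.6 RPM in the chimpanzee line and at 96.1 to 166 RPM in the bonobo lines.

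The families named beforehand did not pass. L1PA2, a young LINE-1 family, was at 36.1 ± 6.06 RPM in bonobo and 27.0 RPM in the chimpanzee line, AluY at 41.7 ± 9.74 and 38.6 RPM, SVA_D at 35.9 ± 9.83 and 35.0 RPM, and LTR5_Hs at 13.2 ± 3.79 and 11.02 RPM. HERVH-int, LTR7 and HERVK-int were not analysed here. By size but without passing, HUERS-P3B was at 6.92 ± 2.02 against 1.52 RPM and L1PBA1_5 at 6.12 ± 3.01 against 1.49 RPM, while HERV4_I was at 3.65 ± 2.87 against 8.93 RPM. HARLEQUINLTR was at 13.4 ± 10.9 against 20.7 RPM, LTR3B at 2.44 ± 0.193 against 5.42, HERVK11DI at 0.943 ± 0.547 against 2.07, LTR70 at 22.1 ± 7.79 against 33.9 and LTR3 at 1.59 ± 0.505 against 2.89 RPM. Of 10 lists tested, young LINE-1 (10 of 10 members above 0; adjusted p = 0.0122) and the PtERV group of ape retroviruses (12 of 12; adjusted p = 0.0189) were higher by camera from limma, with an adjusted p = 0.863 with an estimated correlation for both. Neither passed after median-ratio scaling, with lines as replicates or without any 1 bonobo line. Adjusted over the list alone, 1 young LINE-1 and 3 PtERV families were higher. Members above 0 were common in lists that did not pass too, with 6 of 6 for SVA, 25 of 31 for AluY and 18 of 22 for AluS and AluJ, but 3 of 7 for HERV9 and LTR12. Reads were split between families, so the members of a list are not independent. The lists of HERVH and LTR7 (adjusted p = 0.101), HERVK and LTR5 (0.101), SVA (0.999), AluY (0.279), AluS and AluJ (0.243), HERV9 and LTR12 (0.34), MER41 (0.938) and old LINE-1 (0.243) did not pass. AluY passed fry alone (adjusted p = 0.00662). Camera, which sets a list against the other families, was lower for AluY (median 0.08, mean 0.06), AluS and AluJ (0.04, 0.03) and old LINE-1 (0.10, 0.13), and for HERV9 and LTR12 the median was -0.03 and the mean 0.07. The HERV-W list had 2 tested members, too few for a test. Besides LTR17 it held HERV17, which did not pass, at 5.10 ± 1.22 RPM in bonobo against 5.42 RPM in the chimpanzee line.

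Between the bonobo animals, 1 family passed: HUERS-P3 was at 2.96 RPM in the female line against 0.598 and 1.25 RPM in the male lines (limma adjusted p = 0.0261). After median-ratio scaling 16 passed, and HERV9, at 29.7 against 5.24 and 8.23 RPM, and LTR12E, at 21.6 against 6.20 and 6.32 RPM, were the largest that did not pass as deposited. MER51I was at 17.6 against 7.90 and 4.87 RPM, MER51B at 10.7 against 4.35 and 2.87, and MER57A_I at 12.0 against 4.66 and 4.03 RPM. On the other side, without passing, MER11A was at 10.8 against 34.6 and 19.7 RPM, HERVK at 16.1 against 30.8 and 25.4, HERV4_I at 1.36 against 2.72 and 6.87, HERVK11DI at 0.326 against 1.37 and 1.14, HARLEQUINLTR at 7.54 against 25.9 and 6.60, and L1PB2 at 5.90 against 10.0 and 6.95 RPM. Quantile normalization or no filter left 0 families in limma, with 33 and 45 at an unadjusted p under 0.05. The female line lay at least 1.5-fold beyond the nearest other library at 16 families, the chimpanzee line at 10, C6 at 6 and B1 at 4. C6 and B1 each had the other line of the same male among the libraries compared. These counts moved with the scaling: C6 had 0 after median-ratio scaling, quantile normalization or equal totals, and the female line had 7 after quantile normalization and 10 with equal totals.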

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

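The search for repeat families named for rodents was chosen after the values were seen. RLTR10B and RLTR10C, families with rodent names, were kept out of the comparisons by the filter on low values. The floors of 3 reads were 0.163, 0.171, 0.162 and 0.183 RPM in the female bonobo line, B1, C6 and the chimpanzee line. RLTR10C lay above them in all 4, at 0.814, 0.854, 0.541 and 1.40 RPM in that order. RLTR10B lay above its floor in B1 alone, at 0.228 RPM, and was at 0.109 RPM in the female line, listed at 0 in C6 and at 0.122 RPM in the chimpanzee line. RMER10B, a further family with such a name, passed the filter and was tested, at 1.09, 1.20, 0.271 and 1.58 RPM in the same order. RLTR10C and RMER10B were lowest in C6 and highest in the chimpanzee line, and of the 21 fibroblast markers 14 were lowest in C6 and 10 highest in the chimpanzee line. C6 also had the lowest repeat total, at 6600 RPM, and was lowest at 31 of 31 AluY and 30 of 40 old LINE-1 families. Being lowest in C6 was thus not particular to families with rodent names, but the size of the gap differed. AluY lay at a median of -0.425 log2 units in C6 against the mean of the other libraries. RMER10B fell further, to 5 reads in C6 against 20, 21 and 26 elsewhere, if 1 step is 1 read. The floors take 1 step of the RPM values as 1 read and cover counting error alone.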

How the results depend on the processing

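The alternatives that left out the segment around POU5F1, scaled repeats to 1 total, set lines as replicates without the trend, or left out lines for the list tests were chosen after the data were seen. Each bonobo line left out gave 1 to 197 species genes, the lowest without B1 and 106 without C6, 0 families and 0 family lists. The 197, without the female, rest on the male's 2 lines as replicates, the others on 2 animals. The chimpanzee line, with no replicate, is assumed to vary like bonobo. Of 122 alternatives for the counts and correlations 59 stayed close, and direction was not compared for these. Of 342 for named genes and families 215 kept the call, 127 lost it and 0 changed direction. Of 96 for lists 52 kept it, 44 lost it and 0 changed direction. Of the 48 species genes and families named, 47 lost the call without B1, where the log2 difference was 4.02 for GRAMD2A (4.03 with all lines), -3.39 for PECAM1 (-3.43) and 2.64 for SPINK5 (2.62), but 1.61 for TNNC2 (2.56). Species genes numbered 333 after median-ratio scaling, 77 after quantile normalization, 40 with lines as replicates, 8 with lines and no trend, and 0 without the filter or the trend in limma (2296 and 2029 at an unadjusted p under 0.05). Genes between bonobo animals numbered 8 after quantile normalization and 0 without the filter or the trend (771 and 556). Genes at which a library stood apart numbered 148 for the female line, 174 for B1, 74 for C6 and 474 for the chimpanzee line with a pseudocount of 0.1 TPM, and 52, 40, 10 and 190 at a mean of at least 5 TPM. Species families numbered 2 with a pseudocount of 0.1 RPM, 19 after median-ratio scaling, and 0 without the filter, at 10 RPM, after quantile normalization, with lines as replicates or with equal totals (30, 7, 22, 18 and 30 at an unadjusted p under 0.05). Families between animals numbered 2 with a pseudocount of 0.1 RPM, 2 at 10 RPM, 16 after median-ratio scaling, and 0 without the filter or after quantile normalization (45 and 33). Families standing apart numbered 4 in the female line at 10 RPM, 7 after quantile normalization and 10 with equal totals. In B1 they numbered 8 with a pseudocount of 0.1 RPM and 2 after quantile normalization. In C6 they numbered 13 with that pseudocount, 2 at 10 RPM, and 0 after median-ratio scaling, quantile normalization or equal totals. In the chimpanzee line they numbered 18 and 4 with that pseudocount and at 10 RPM. An estimated correlation left 0 gene lists in both comparisons and 0 family lists, and fry 0, 0 and 1. The estimated correlation had too little spread to rest on, so its losses, which are among the 44, say little about the lists. Family lists numbered 0 after median-ratio scaling or with lines as replicates. Mean Pearson correlations fell from 0.982 to 0.972 between bonobo lines and from 0.967 to 0.952 between species with a pseudocount of 0.1 TPM, and to 0.977 and 0.960 at 5 TPM. For families they were 0.960 and 0.950 at 10 RPM. The cause was not tested. A fit with the animal as a block gave no estimate, since limma's duplicateCorrelation returned 0 correlations over 12061 genes with 4 libraries and 2 coefficients, and a count test on reads was not run because whole reads were not recovered. No paired analysis was possible because replicate numbers only name the samples and the species share 1 number. Depth behind TPM is unknown, so the limit it sets on low TPM values is unknown too.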

Other observations

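The tests below, except the test for deletions, were chosen after the result was seen, on gene and family lists fixed beforehand. The lines B1 and C6 of the same male differed in gene groups fixed beforehand, in a comparison of 1 library with 1 library over 18 lists and no replicate check. Random lists were drawn gene by gene, so the percentiles below leave out correlation within a list. For p53 targets that correlation was estimated at 0.681 in the fit of the bonobo animals, though 3 lines are too few for a firm estimate. Fibroblast markers were higher in B1 at 18 of 21 genes, with a median of 0.40 log2 units, above all 10000 random lists matched on mean expression (percentile 100). Ribosomal protein genes were higher at 60 of 73, with a median of 0.10 (percentile 99.9). The p53 targets were lower in B1 at 22 of 24 genes, with a median of -0.35, and glycolysis genes at 18 of 26, with a median of -0.20 (percentile 0 for both). Wnt targets had a median of 0.25 (percentile 100) with 10 of 17 higher in B1, blood cell markers -0.49 (percentile 1.4) with 1 of 8 higher, and core pluripotency genes -0.08 (percentile 2.1) with 11 of 26 higher. SESN1, a stress-response gene, was at 17.4 TPM in B1 and 25.9 TPM in C6. LCK, a kinase gene of T cells, was at 93.4 to 178 TPM over the 4 lines. It does not stand for the blood cell list as a whole. Of other T-cell genes in that list, CD3D was at 17.5 to 30.8 TPM and CD4 at 2.22 to 7.33 TPM. CD3G reached at most 0.262 TPM, and CD2 was listed at 0 in all 4 lines. PTPRC, a general marker of the list, reached at most 0.0611 TPM. Among repeats, the HERV9 and LTR12 list was higher in the female bonobo line than in the male's lines (camera from limma, adjusted p = 0.00827, and adjusted p = 0.988 with an estimated correlation), with a median of 1.10 log2 units over 7 families. The lists of AluY (adjusted p = 0.00827; median -0.01, mean 0) and of AluS and AluJ (adjusted p = 0.0263; median 0.01, mean 0.02) were lower by the same camera test, which sets a list against the other families. Both had an adjusted p = 0.988 by camera with an estimated correlation. At all 31 AluY and all 22 AluS and AluJ families B1 was highest and C6 lowest, so the female line lay between them.

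The 219 genes called between the species, mesendoderm genes among them, set 1 chimpanzee line against 2 animals. A loss of chimpanzee reads on a reference stays open: of the genes at which that library stood apart 51.2 percent were lower, but TPM scales every library to 1 total, which hides an overall loss. The state of single cultures may account for part of the mesendoderm difference: B1 and C6 of 1 animal differed by a median of 1.029 log2 units. B1 was higher at 11 of 15 genes, and the median lay above all 10000 random lists. C6 lay above the chimpanzee line by a median of 0.276 (percentile 99.6), but at 9 of 15 genes. The random lists hold genes drawn independently, so these percentiles leave out correlation within a list. A difference between the species stays open without a second chimpanzee line. Of the 3 ways to set 1 animal alone, 1 gave as many genes (219, the highest other 0), and 3 splits are too few for a share under 0.05.

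Most genes of the segment around POU5F1 were near 0 TPM, 86 of 105 with a mean under 1 TPM and 4 with at least 10 TPM. That its genes are silent is argued against by its members of families that every cell needs, RPS18, MRPS18B, LSM2 and PFDN6, which reached at most 0.456 TPM, while 167 genes of those families elsewhere had a median of 204.4 TPM and 2 of them were under 1 TPM in every library. The 50 listed genes around POU5F1 had a median of 0.00484 TPM, below all 14720 such windows elsewhere (lowest 0.0227). Reads lost in alignment or counting, as where a reference holds the segment more than once, are a candidate explanation. No biological explanation beyond silence was tested.

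The 30 genes lower in the female bonobo line may be lost to deletions, to the clone or to the animal. Their 58 nearest tested neighbours, leaving out any among the 30 themselves, had a median of -0.045 log2 units. Counting all neighbours, 6 of the 30 genes (20 percent) had a low one, which lies at the bound set beforehand, so deletions stay open. The same share was not computed for other genes, and a deletion of a single gene would leave its neighbours unchanged, so the test cannot decide. Sex as the cause of the whole set is argued against by the female chimpanzee line, in which 6 of the 30 were also lower, though that line is of another species. With 1 line of the female, the clone and the individual cannot be told apart.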
